A study of Arabidopsis thaliana with 4 samples.

How the data were processed

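Single-colour Agilent arrays of 4 Arabidopsis shoot samples were used, 2 from control plants and 2 from plants inoculated with Mucor sp., with 1 array per sample and leaves of 3 plants per sample. Per the labels, seedlings were inoculated in vitro at the 2-leaf stage, 15 days after germination, and grown for 5 days with 16 hours of light, at 21 °C by day and 17 °C by night and 50% humidity, while the titles give 10 days. The group and number of each sample came from its title. The numbers 1 and 2 follow the position of the array on its slide, and the labels do not say that they pair samples.

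Per the file headers, the scanner files were made by the authors with Agilent Feature Extraction 10.7.3.1, which corrected each spot's intensity for background and for trends across the array but did not normalize it between arrays. The submitters' processing notes name the same software without a version. The authors also deposited a matrix of log2 values with 33300 rows. From its values, this matrix is log2 signal minus the array's 75th percentile, with each row centred on its median. Its columns have medians of -0.18 and -0.15 for the controls and 0.05 for each inoculated sample. Both inoculated columns of the deposited matrix are identical in all 33300 rows and follow the first inoculated array, with a median absolute difference of 0.0115 from it and 0.544 from the second once the first control was subtracted. The matrix was therefore used only as an alternative, with 2 control samples and 1 inoculated sample. This alternative matrix was not filtered for dim probes and the first row of each gene was taken, giving 33138 features. In it, 3 cells held a month and a number in place of a value, and their rows were left out.

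From the scanner files, log2 of the processed signal minus the array's 75th percentile over probes other than controls was computed, spots of 1 probe were averaged, and 25 probes with an outlier flag were left out. No spot was saturated. For each gene the probe with the highest mean signal was used, and a gene was tested if that probe was well above background on both arrays of at least 1 group, which left 22497 of 33084 features. Of the genes tested, 7234 had several probes. For 22 of the 538 called ones with several probes, another probe well above background on both arrays of at least 1 group had the opposite sign. Dimmer probes were not counted for this. Probes were named through their RefSeq accession in a table of gene names of assembly TAIR10.1 (34348 of 43603 probes), or else through the Entrez number in the authors' matrix (2078). The remaining 7177 probes were kept as features under the array's own identifier and are not named here. The grid files cite the TAIR10 annotation, and no coordinates are given because the builds are not stated to be the same.

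Groups were compared with lmFit and eBayes in limma 3.58.1 (R 4.3.3), two-sided, as inoculated minus control, with Benjamini-Hochberg adjustment and a threshold of 0.05. No slide term could be fitted because each slide held 1 group. Where a probe was not well above background on any array of a group, its fold is a lower bound. The bound sets the bright group's mean against the dim group's mean of, for each array, the higher of the probe's own signal and the lowest signal among probes well above background. Before the data were examined, the test, the rule for naming genes and 29 gene lists with 527 loci were fixed, of which 483 loci were measured. List shifts were tested with limma's camera at a preset correlation of 0.01 between genes, with an estimated correlation and with fry beside it. The rule for naming genes takes the 12 largest increases and 12 largest decreases among called genes measured on all 4 arrays whose groups do not overlap. It adds up to 4 genes per direction with the largest lower bound and up to 4 genes of smallest p in each list, with all measured genes of the strigolactone list. Only features matched to a locus were named. Some genes that the rule names are not reported here. LDOX, EXPA10, BHLH100 and PRR9 lie outside this rule, as do the genes named only in the closing observations, and were named after their values were seen.

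The alternatives were quantile normalization, the median in place of the 75th percentile, normexp background correction (offset 50) with quantile normalization, the authors' matrix, no filter on dim probes, a filter asking for all 4 arrays, the mean of all probes of a gene, eBayes with trend and robust options, the array position as a block, a 2-fold minimum, an estimated correlation and each array left out in turn. Normexp was run on the median spot signal because the files hold no mean spot signal. Its offset, added to every signal, shrinks the folds of dim genes, so smaller medians with normexp partly follow from the offset. Array weights and a test of matched features alone were added after seeing the data. The fits were checked on simulated arrays whose spread was drawn from the variances of the real features, shuffled without regard to signal. Those variances come from 2 arrays per group and noise was added again, so the simulated spread is more uneven than the real one. Of 200 features changed 16-fold among 22497 in a simulated comparison of these groups, 150 were called, with 4 false calls. Of 200 changed 4-fold, 0 were called, and of 200 changed 2-fold, 0 were called. With 7499 features changed by mixed amounts, 3778 were called in the right direction, with 171 false calls. In the data 7393 features had an unadjusted p under 0.05 in limma, and the smallest called fold was 1.90. The runs with 200 changed features therefore set no limit on the folds that can be called. Families and further lists in the closing observations were tested in Python 3.11.15 with scipy 1.17.1.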

Results

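Gene expression was measured in shoots of Arabidopsis thaliana seedlings that had been inoculated with a fungal endophyte, Mucor sp., and in shoots of seedlings left without inoculation. Mucor is a genus of mostly soil-living moulds of the Mucoromycota, and an endophyte is a microbe that lives inside a plant. There were 2 control samples and 2 inoculated samples, each made from the leaves of 3 plants and hybridised to its own single-colour array. The sample titles placed the harvest 10 days after inoculation, while the treatment protocol gave 5 days in the growth chamber. The age label of both groups gave 20 days, and the seedlings had been inoculated 15 days after germination. The arrays carried 43603 distinct probes other than controls, of which 72.2% and 71.9% were well above background on the control arrays and 66.6% and 72.4% on the inoculated arrays. The first inoculated array was dimmer, with a 75th percentile signal of 461 intensity units against 1265 to 1897 on the other arrays. With 2 arrays per group, their number limits the precision of every value that follows, and the labels do not say whether the samples came from separate experiments, so p-values measure only the spread between these samples.

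The comparison asked which shoot genes differed between inoculated and control plants. Of 16 measured genes of flavonoid and anthocyanin synthesis, 12 were called lower in inoculated shoots and 4 were not called. Among those measured on all 4 arrays, DFR (AT5G42800, dihydroflavonol reductase) changed most and was 53.9-fold lower, with a log2 fold change of -5.75 ± 0.66 (SE, n = 2 per group). Lower alongside it were the light-stress genes ELIP2 (AT4G14690), by 32.7-fold, and ELIP1 (AT3G22840), with a log2 fold change of -4.33. Genes known to respond to darkness and low sugar were among the largest increases. DIN1, also called SEN1 (AT4G35770), was 46.7-fold higher and ASN1 (AT3G47340), which encodes an asparagine synthetase, was 31.6-fold higher. The largest increase among genes measured on all 4 arrays was that of ST2A (AT5G07010), a sulfotransferase that acts on hydroxylated jasmonate, at 87.9-fold.

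Of 22497 features tested with limma, 1789 passed an adjusted p of 0.05, of which 828 were higher and 961 lower after inoculation. Matched to a locus were 19669 of the features tested, and 712 of these were called higher and 872 lower. Every called gene had both inoculated values on the same side of both control values. Among all features 65.9% did so, against 33.3% expected by chance. The groups separated along the first principal component, which held 73.1% of the variance. Across features, the 2 control arrays correlated at r = 0.986, the 2 inoculated arrays at r = 0.975, and arrays of different groups at r = 0.927 to 0.956. These are correlations across genes, which are not independent replicates. Both controls lay on 1 slide and both inoculated samples on another, so slide and group cannot be told apart. The number of calls varied with the array left out and with the filter. A fit without an array takes its spread from the other group's pair alone. The inoculated pair differed more than the control pair (SD of the difference 0.62 against 0.45). Counts without an array also reflect which pair sets the spread, and do not show that the calls depended on that array. Without control 1 limma called 0 features (3676 at an unadjusted p under 0.05), without control 2 it called 0 (5272 unadjusted), and without the filter on dim probes it called 0 (6033 unadjusted), while without inoculated 1 it called 2083 and without inoculated 2 it called 4232.

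**Figure D1:**
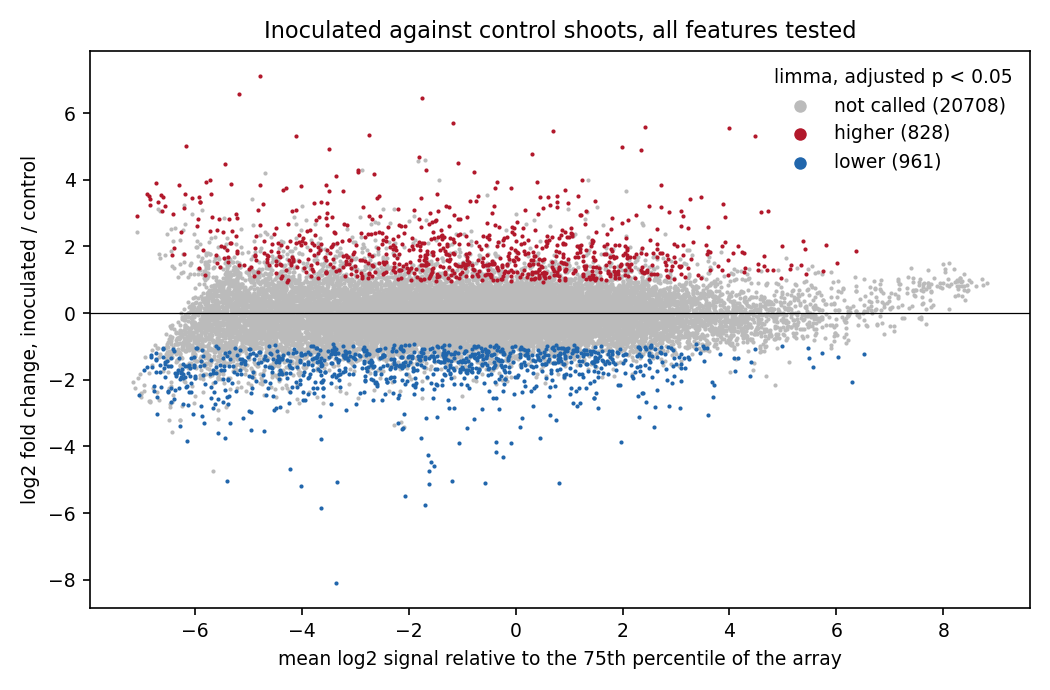
Each point is a feature, with its mean log2 signal over the 4 arrays (relative to the array's 75th percentile) on the horizontal axis and the log2 fold change of inoculated over control on the vertical axis; red and blue points passed an adjusted p of 0.05 in limma. The 828 features called higher and 961 called lower spread over most of the signal range, and the brightest features, at a mean of 7 or more, lie mostly above 0 (64 of the 73 outside the photosynthesis list).

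The other large increases fell on genes of several kinds. RTFL21 (AT1G67265), of a family of small growth-regulating peptides, was 51.9-fold higher, and CCL (AT3G26740) was 39.4-fold higher. MIOX2 (AT2G19800), a myo-inositol oxygenase, was 19.4-fold higher, and NUDT8 (AT5G47240), a nudix hydrolase, 18.8-fold higher. Also among the 12 largest increases were AT3G62550, AT1G56300, AT5G43440, AT1G53903 and AT5G02540, with folds from 15.8 to 29.9. SAG12 (AT5G45890), a cysteine protease that marks senescing leaves, was not well above background on either control array and was at least 22.5-fold higher after inoculation (limma adjusted p = 0.0127). On the same basis CYP96A5 (AT2G21910) was at least 35.7-fold higher, ABR1 (AT5G64750), an ERF-family transcription factor, at least 30.2-fold higher, and PIL2 (AT3G62090), a phytochrome-interacting factor, at least 11.6-fold higher. Other large decreases were those of AT4G27360 (22.3-fold), the MYB-like gene RVE2 (AT5G37260, 19.1-fold), AT2G27420 (17.8-fold) and AT5G42760 (15.1-fold). AT1G26790, a gene of the Dof transcription factor family, was not well above background on the inoculated arrays and was at least 99.6-fold lower there. AT1G03495 was likewise at least 17.0-fold lower and AT4G13580 at least 5.42-fold lower.

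All 16 measured genes of the flavonoid and anthocyanin list were negative, and 12 of them were called lower, with a median log2 fold change of -3.54 (-1.72 with normexp). Chalcone synthase (CHS, AT5G13930), the entry enzyme of the pathway, was 34.2-fold lower (log2 fold change -5.10 ± 0.21, limma adjusted p = 0.0202). Flavonol synthase FLS1 (AT5G08640) was 34.5-fold lower, F3H (AT3G51240) 13.3-fold lower, and GSTF12 (AT5G17220), which carries anthocyanins to the vacuole, 35.0-fold lower. The anthocyanin glycosyltransferase UGT79B1 (AT5G54060) was at least 38.0-fold lower, being not well above background on either inoculated array. Outside the list, CHIL (AT5G05270), a partner protein of chalcone synthase, was 14.9-fold lower. AT4G22870, which lies beside LDOX (AT4G22880) and resembles it, was 45.1-fold lower; the array cannot exclude that the probes of the pair share target. As a group the list was lower than the other genes (camera adjusted p = 4.76e-11, and adjusted p = 0.492 with an estimated correlation between its genes). Its members also moved 1 way on balance by fry, which does not compare them with other genes (adjusted p = 0.000914). Adjusted over the list alone, all 16 were lower.

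The phenylpropanoid and lignin list, which supplies the precursors of flavonoids, held 17 measured genes, of which 8 were lower, 0 higher and 9 not called. PAL1 (AT2G37040), the first enzyme of the pathway, was 5.28-fold lower and the ligase 4CL3 (AT1G65060) 9.05-fold lower. The ligase 4CL2 (AT3G21240) was 3.01-fold lower and CAD4 (AT3G19450), of monolignol synthesis, 3.40-fold lower. The list's median log2 fold change was -0.91 (camera adjusted p = 3.78e-05, and adjusted p = 0.601 with an estimated correlation; fry adjusted p = 0.0217), with 12 genes lower when adjusted over the list alone.

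Aliphatic glucosinolates are sulfur-rich defence compounds made from methionine. Of the 20 measured genes of their synthesis, 15 were lower, 5 were not called, and all 20 had negative log2 fold changes, with a median of -1.47. The side-chain oxygenase gene FMOGS-OX3 (AT1G62560) was 5.64-fold lower, MAM3 (AT5G23020), of side-chain elongation, 3.91-fold lower, UGT74C1 (AT2G31790) 2.75-fold lower and IIL1 (AT4G13430) 2.69-fold lower. The list was lower as a group (camera adjusted p = 1.44e-10, and adjusted p = 0.664 with an estimated correlation; fry adjusted p = 0.0553), and all 20 genes were lower when adjusted over the list alone. Genes of camalexin and indole glucosinolate synthesis did not pass as a group (22 measured, median -0.23, camera adjusted p = 0.331), and their median was -0.05 without inoculated 1 and -0.46 without inoculated 2, with 2 genes called higher and 3 lower in the latter. Within that list CYP71A13 (AT2G30770), of camalexin synthesis, was called and was at least 3.54-fold lower. PAD3 (AT3G26830), the last step of camalexin synthesis, had a log2 fold change of -1.49 and the myrosinase PEN2 (AT2G44490) one of 1.49, and neither passed the test (adjusted p = 0.0642 and 0.066); CYP79B3 (AT2G22330) had -0.62.

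**Figure D2:**
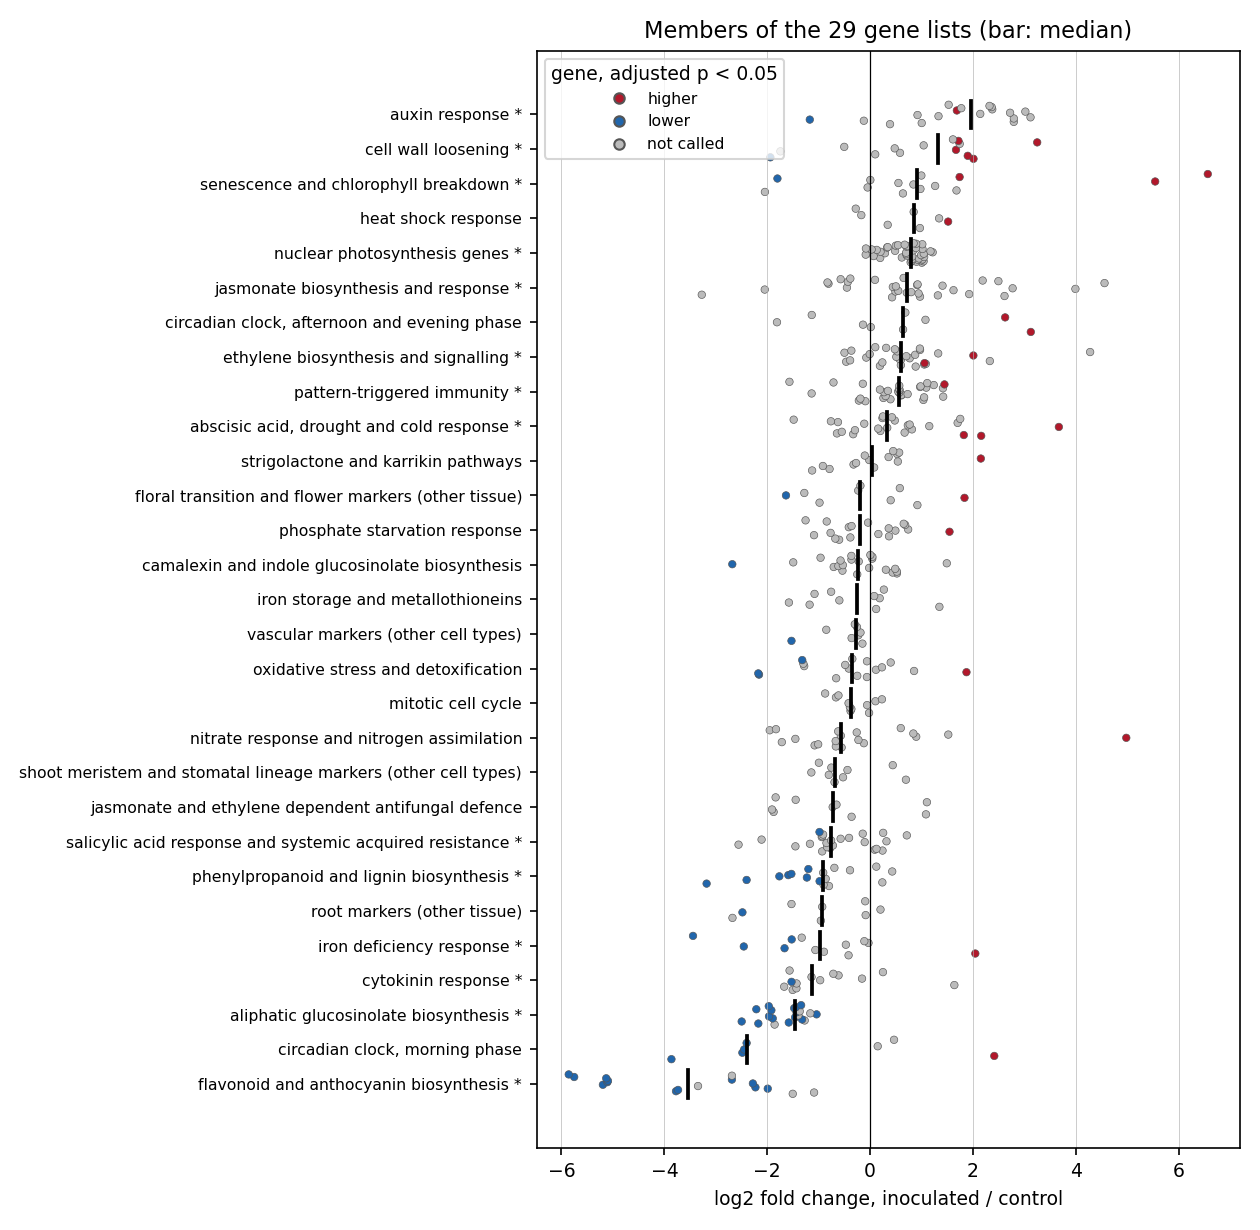
Each point is a measured gene of 1 of the 29 lists, with its log2 fold change of inoculated over control on the horizontal axis; the bar is the list's median, red and blue mark genes called higher and lower by limma, and an asterisk marks the 14 lists whose shift passed an adjusted p of 0.05 in camera with its preset correlation. The flavonoid list has the lowest median (-3.54, or -1.72 with normexp) and the auxin list the highest (1.96).

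In all, 14 of the 29 lists shifted with camera's preset correlation, 8 upward and 6 downward. With a correlation estimated from the arrays, camera called 0 of the 29, and the smallest adjusted p was 0.492. Only the flavonoid list had an unadjusted camera p under 0.05 (0.017, against 1.64e-12 at the preset correlation). Its estimated correlation was -0.06, below the preset 0.01, so a higher correlation does not account for that rise. The cell wall loosening and senescence lists also had estimated correlations below the preset (-0.04 and -0.03). Their unadjusted camera p still rose, to 0.0739 and 0.0704. The lost calls therefore do not measure correlation between genes alone. With an estimated correlation, camera takes its p from the 2 residual degrees of freedom of this fit, not from the number of features. The 0 calls there cannot decide whether a list shifted. Other called lists had estimated correlations far above the preset, such as 0.86 for auxin, 0.80 for photosynthesis and 0.51 for both cytokinin and jasmonate. Their camera p at the preset may be too small. By fry, 4 of the 14 passed (the flavonoid, phenylpropanoid, cell wall loosening and senescence lists) and the other 10 did not, with adjusted p from 0.0553 to 0.443, while the morning clock genes, which camera did not call, passed (0.0404). Of the 15 lists that camera did not call, 10 passed in at least 1 other setting. Without control 1, or without control 2, limma called 0 members of every list, since it called 0 features in all (3676 and 5272 at an unadjusted p under 0.05). In the authors' deposited matrix, every upward list except the photosynthesis genes lost its call. That matrix was not filtered for dim probes and gave 1 inoculated sample. The median of its features was 0.26, against -0.04 in the main setting, a higher background for upward lists.

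Lists related to growth went in different directions. In the auxin response list, 16 of 18 measured genes were positive, with a median of 1.96 (camera adjusted p = 0.000131, and adjusted p = 0.664 with an estimated correlation). The estimated correlation between its members was 0.86, far above the preset 0.01, and fry gave an adjusted p of 0.346. Over all genes, 1 member was called higher, SAUR15 (AT4G38850, 3.22-fold), and 1 lower, while adjusted over the list alone 12 were higher and 1 lower. GH3.3 (AT2G23170) had a log2 fold change of 2.80 and IAA19 (AT3G15540) one of 3.12, with adjusted p of 0.0575 and 0.0657. Without control 1 the auxin median was 1.29, and without inoculated 2 limma called 7 auxin genes higher and 1 lower. Cell wall loosening genes had a median of 1.33, with 5 of 14 higher and EXPA10 lower (camera adjusted p = 0.00396, and adjusted p = 0.601 with an estimated correlation; fry adjusted p = 0.0127; 9 higher and 1 lower over the list alone). Its median was 0.59 with normexp, and 8 were higher and 2 lower without inoculated 2. Among them the wall-remodelling genes XTH18 (AT4G30280), XTH17 (AT1G65310) and XTH19 (AT4G30290) were 9.52-, 3.73- and 3.29-fold higher, and the expansin EXPA11 (AT1G20190) was 4.03-fold higher. The cytokinin response list was lower (13 measured, median -1.14, camera adjusted p = 0.0154, and adjusted p = 0.665 with an estimated correlation). Its single call was the response regulator ARR8 (AT2G41310), 2.88-fold lower, and 5 members were lower over the list alone; ARR4 (AT1G10470), ARR16 (AT2G40670) and CRF5 (AT2G46310) had log2 fold changes of -1.50, -1.43 and -0.97. The cytokinin call ended without control 1 (adjusted p = 0.0644) and without inoculated 2 (0.052, 2 genes called lower), while 4 genes were called lower without inoculated 1.

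Nuclear photosynthesis genes had 0 of 42 members called by limma, over all genes or over the list alone (5 at an unadjusted p under 0.05), but 40 of 42 were positive, with a median of 0.80 (camera adjusted p = 1.11e-05, and adjusted p = 0.665 with an estimated correlation). The smallest p in the list belonged to PSBQ2 (AT4G05180), with a log2 fold change of 1.02 ± 0.25, followed by PSAD2 (AT1G03130) at 1.01, PSAN (AT5G64040) at 0.90 and LHCA3 (AT1G61520) at 1.05. These genes are among the brightest on the array, and the 73 features outside the list with a mean signal of 7 or more had a median log2 fold change of 0.71. After quantile normalization the list's median was 0.17 and its call ended (camera adjusted p = 0.0693), and with normexp the median was 0.20 and 1 gene was called higher. Without inoculated 1 the median was 0.30 and without inoculated 2 it was 1.24, with 23 of the 42 genes called higher.

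Defence lists went in different directions. Of 24 measured genes of the salicylic acid list, 1 was lower, SARD4 (AT5G52810, 1.98-fold), and the median was -0.77 (camera adjusted p = 0.039, and adjusted p = 0.664 with an estimated correlation; 0 called over the list alone and 11 at an unadjusted p under 0.05). The pathogenesis-related genes PR2 (AT3G57260) and PR5 (AT1G75040) had log2 fold changes of -2.11 ± 0.50 and -1.45 ± 0.32, and NIMIN2 (AT3G25882) one of -0.85; none passed the test over all genes. The jasmonate list had a median of 0.71 over 31 genes (camera adjusted p = 0.00872, and adjusted p = 0.67 with an estimated correlation), with 0 genes called over all genes and 0 over the list alone by limma (13 at an unadjusted p under 0.05); 23 were positive. CYP94B3 (AT3G48520) and CYP94C1 (AT2G27690), which break down jasmonoyl-isoleucine, had log2 fold changes of 4.56 ± 1.09 and 3.99 ± 0.95. LOX3 (AT1G17420), of jasmonate synthesis, had 2.62 ± 0.51, and JMT (AT1G19640), which methylates jasmonate, had -3.27 ± 0.63, with adjusted p of 0.0512 and 0.051. The salicylic acid call ended without control 2 (adjusted p = 0.15) and without inoculated 1 (0.0976, median -0.43), while without inoculated 2 it held (0.0021) with 10 genes called lower. The salicylic acid median was also -0.43 with normexp. The jasmonate call ended without inoculated 2 (0.412, median 0.29, 3 genes called higher and 5 lower), and without inoculated 1 the jasmonate median was 1.13, with 7 higher and 1 lower.

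Of the 9 measured antifungal defence genes that depend on jasmonate and ethylene, 0 were called by limma over all genes or over the list alone (1 at an unadjusted p under 0.05), and the list missed the threshold (median -0.73, camera adjusted p = 0.325). Without control 2 the median was -0.46. Without inoculated 2 it was -1.13, limma called 4 of them lower and the list passed (0.0233), as it did in the authors' matrix (0.0417). PDF1.2B (AT2G26020) and PDF1.3 (AT2G26010), plant defensins, had log2 fold changes of -1.91 and -1.88, PR4 (AT3G04720) had -0.73 and ERF1 (AT3G23240) had 1.11. The ethylene list was higher (29 measured, median 0.60, camera adjusted p = 0.0016, and adjusted p = 0.664 with an estimated correlation), with 2 genes called higher over all genes and over the list alone, among them the receptor gene ETR2 (AT3G23150), at 4.03-fold. ACS8 (AT4G37770), well above background on 1 of the 2 control arrays, had a log2 fold change of 4.28 ± 1.02 and the receptor gene ERS1 (AT2G40940) one of 0.77, and neither passed the test. The ethylene median was 0.26 without control 1 and 0.94 without control 2, and 5 genes were called higher without inoculated 2 against 1 higher and 1 lower without inoculated 1. In the pattern-triggered immunity list the flagellin receptor FLS2 (AT5G46330) was 2.73-fold higher and the other 30 measured genes were not called; 0 passed over the list alone (9 at an unadjusted p under 0.05). Its median was 0.57 (camera adjusted p = 0.0195, and adjusted p = 0.664 with an estimated correlation). EFR (AT5G20480) had a log2 fold change of 1.24, PROPEP1 (AT5G64900) one of -0.71, and PROPEP3 (AT5G64905), not well above background on the inoculated arrays, was at least 1.38-fold dimmer there (adjusted p = 0.0513). The immunity call also ended without the filter (0.055), without control 1 (0.0868, median 0.24) and without inoculated 1 (0.21, median 0.14). In that list 4 genes were called higher without inoculated 1, and 5 higher and 2 lower without inoculated 2.

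The strigolactone and karrikin list was included because the plant's response to this fungus has been studied for that hormone pathway. Of 14 measured genes, 1 was called, BRC1 (AT3G18550), a repressor of shoot branching, with a log2 fold change of 2.15 ± 0.37 (adjusted p = 0.0441) and well above background on 1 of the 2 control arrays. D27 (AT1G03055) and MAX1 (AT2G26170), of strigolactone synthesis, had log2 fold changes of -1.13 ± 0.23 and -0.92 ± 0.18 with adjusted p of 0.0556 and 0.0524, and were lower when adjusted over the list alone. The repressor SMXL6 (AT1G07200) had -0.79, SMXL7 (AT2G29970) -0.32 and SMXL8 (AT2G40130) -0.27. The receptor gene D14 (AT3G03990) had -0.02, the F-box gene MAX2 (AT2G42620) 0.54, MAX4 (AT4G32810), whose 2 probes disagreed in sign, 0.53 and LBO (AT3G21420) 0.36. On the karrikin side, KAI2 (AT4G37470) had 0.57, SMAX1 (AT5G57710) 0.45, KUF1 (AT1G31350) 0.08 and DLK2 (AT3G24420) -0.10. As a group these genes did not pass camera (median 0.03, adjusted p = 0.688); the median was -0.09 without control 1, 0.41 without control 2 and 0.14 without inoculated 2.

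Core clock genes differed strongly in both directions. The morning MYB genes LHY (AT1G01060), CCA1 (AT2G46830), RVE8 (AT3G09600) and RVE1 (AT5G17300) were 14.5-, 5.59-, 5.46- and 5.28-fold lower in inoculated shoots. PRR9, a morning gene, had a log2 fold change of 2.42 ± 0.40 and was called higher, as were GI (AT1G22770) and PRR5 (AT5G24470), which peak later in the day, at 8.73- and 6.18-fold. Of the morning list, 4 of 7 genes were lower and 1 higher over all genes and over the list alone, and of the afternoon and evening list 2 of 9 were higher, with 1 more lower over the list alone. BOA (AT5G59570) had -1.13 and LUX (AT3G46640), with 1 of its 3 probes of opposite sign, had 1.08, and neither passed over all genes. With members going both ways, neither list passed camera (adjusted p = 0.0732 and 0.128, medians -2.40 and 0.64), although both passed without control 1 (0.0367) and without inoculated 1 (0.0365); the later list's median was 0.34 without control 1 and 0.42 without inoculated 2. The labels give no time of harvest.

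**Figure D3:**
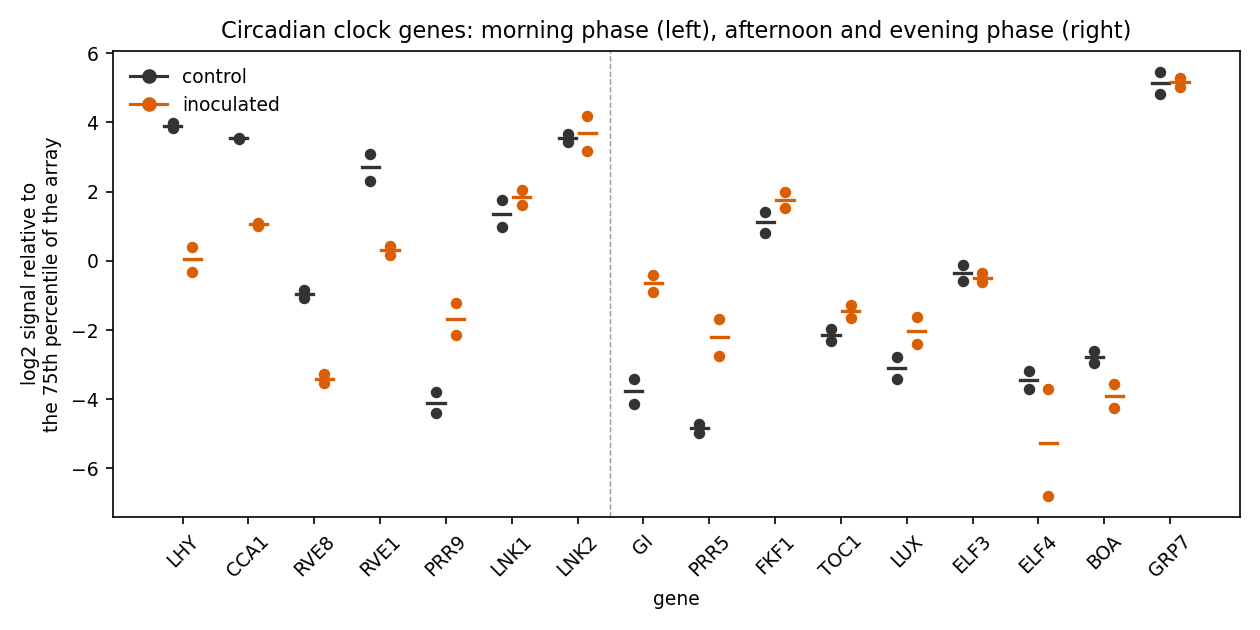
Points are single arrays and bars group means of log2 signal relative to the array's 75th percentile, for 16 clock genes in control (dark grey) and inoculated (orange) shoots, with morning genes left of the dashed line. LHY lies at 3.98 and 3.84 in the control arrays and at 0.41 and -0.31 in the inoculated arrays, while GI lies at -4.13 and -3.41 in the control arrays and at -0.89 and -0.40 in the inoculated arrays.

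Senescence and nutrient lists held several of the strongest single changes. In the senescence and chlorophyll breakdown list, SAG12, DIN1 and the pheophytinase gene PPH (AT5G13800, 3.35-fold) were higher, and SAG29 (AT5G13170) was at least 1.53-fold lower, out of 14 measured. The list's median was 0.91 (camera adjusted p = 0.00328, and adjusted p = 0.601 with an estimated correlation; fry adjusted p = 0.0127), and 6 genes were higher and 1 lower over the list alone. The iron deficiency list was lower (12 measured, median -0.98, camera adjusted p = 0.00961, and adjusted p = 0.664 with an estimated correlation). The nicotianamine synthase genes NAS1 (AT5G04950) and NAS4 (AT1G56430) were 10.9- and 3.17-fold lower, the phloem iron transporter gene OPT3 (AT4G16370) was 2.87-fold lower, and BHLH100 was also called lower. The reductase gene FRO3 (AT1G23020) went the other way, 4.13-fold higher; over the list alone 6 were lower and 1 higher. The list's median was -0.24 with normexp, -0.58 in the authors' matrix and -0.47 when all 4 arrays had to be above background. Genes of iron storage and metallothioneins did not pass camera (10 measured, 0 called by limma over all genes or the list alone, 3 at an unadjusted p under 0.05, median -0.26, adjusted p = 0.583). Without inoculated 1 their median was -0.80, with 1 gene called higher and 1 lower, and without inoculated 2, 1 was called higher. NAS3 (AT1G09240) had a log2 fold change of 1.35, VTL2 (AT1G76800) -1.58, VTL1 (AT1G21140) -1.17 and the ferritin gene FER3 (AT3G56090) -1.08.

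The nitrogen list did not pass (19 measured, median -0.57, camera adjusted p = 0.352), although ASN1 was called higher. GDH2 (AT5G07440) had a log2 fold change of 1.52, UPM1 (AT5G40850) -1.95 and ASN2 (AT5G65010) -1.83 (1 of its 2 probes had the opposite sign), and over the list alone 5 genes were higher and 5 lower. In the phosphate starvation list (18 measured, median -0.20 and from -0.31 to -0.11 with each array left out, camera adjusted p = 0.713) the single call over all genes and over the list alone was GDPD1 (AT3G02040), 2.92-fold higher by its brightest probe while its other probe had the opposite sign. The phosphate transporter genes PHT1;1 (AT5G43350), PHT1;2 (AT5G43370) and PHT1;4 (AT2G38940) had -0.84, -1.25 and -0.77, PHT1;2 being well above background on 1 of the 2 inoculated arrays. In the oxidative stress list (17 measured, median -0.34, camera adjusted p = 0.158; median -0.58 and adjusted p = 0.0367 without control 1, median -0.21 without control 2) the catalase genes parted, CAT3 (AT1G20620) being 3.67-fold higher and CAT2 (AT4G35090) 2.49-fold lower; 1 of the 2 CAT2 probes had the opposite sign. The glutathione transferase gene GSTU24 (AT1G17170) was 4.47-fold lower and GSTU25 (AT1G17180) at least 1.21-fold lower, and over the list alone 2 genes were higher and 4 lower. The abscisic acid, drought and cold list was higher (25 measured, median 0.33, camera adjusted p = 0.039, and adjusted p = 0.683 with an estimated correlation). Its 3 calls, over all genes and over the list alone, were the cold regulator CBF3 (AT4G25480, 12.7-fold) and the dehydrin genes COR47 (AT1G20440, 4.47-fold) and ERD10 (AT1G20450, 3.54-fold); ABI1 (AT4G26080) had a log2 fold change of 0.74. This list's call ended in 8 settings besides the estimated correlation, including quantile normalization (adjusted p = 0.0541), and without control 1 (0.138, median 0.12) or inoculated 2 (0.558, median 0.22); its median was 0.59 without control 2, 0.68 without inoculated 1 and 0.19 with normexp. Without inoculated 1, 5 genes were called higher and 1 lower, and without inoculated 2, 3 and 3. Among 7 measured heat shock genes, BAG6 (AT2G46240) was 2.87-fold higher over all genes and over the list alone, and the list did not pass (median 0.85, camera adjusted p = 0.143), though it did without inoculated 1 (0.033, median 1.27), and its median was 0.42 without control 1 and 0.12 without inoculated 2; HSP101 (AT1G74310), HSP70 (AT3G12580) and HSP90.1 (AT5G52640) had 0.97, 1.34 and 0.85.

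Markers of other tissues and cell types were examined as lists too, since the samples were leaves. Of 8 measured root markers, CASP1 (AT2G36100), of the Casparian strip, was called lower, with a log2 fold change of -2.48, though well above background on 1 of the 2 inoculated arrays. COBL9 (AT5G49270) was at least 1.90-fold dimmer in inoculated shoots without passing the test, RHD6 (AT1G66470), also well above background on 1 of those arrays, had -0.96, and the list missed the threshold (median -0.94, camera adjusted p = 0.0664; 3 lower over the list alone), although it passed without control 1 (0.0181) and without inoculated 1 (0.00889), each time downward, while its median was 0.32 in the authors' matrix. Among 9 floral genes, SOC1 (AT2G45660), a promoter of flowering, was 3.57-fold higher and AG (AT4G18960) at least 1.15-fold lower, while SEP3 (AT1G24260) had 0.92 and FT (AT1G65480), well above background on 1 of the 2 inoculated arrays, -0.98. The floral list did not pass (camera adjusted p = 0.846, with an upward direction against a median of -0.19, which ranged from -0.45 to 0.29 with each array left out; 2 higher and 2 lower over the list alone). Of 8 vascular markers the phloem sucrose transporter gene SUC2 (AT1G22710) was 2.88-fold lower over all genes and over the list alone, all 8 were negative, and the list missed the threshold (median -0.28, camera adjusted p = 0.0557) but passed in 4 other settings (0.0114 to 0.0422); XCP1 (AT4G35350), VND7 (AT1G71930) and CESA4 (AT5G44030) had -0.85, -0.36 and -0.30. Meristem and stomatal lineage markers had 0 of 9 called by limma over all genes (4 at an unadjusted p under 0.05) and 3 lower over the list alone, with a median of -0.69 (camera adjusted p = 0.0732). MUTE (AT3G06120), TMM (AT1G80080), KNAT1 (AT4G08150) and SPCH (AT5G53210) had -1.14, -0.80, -0.75 and -0.99. The mitotic list had 0 of 11 called by limma over all genes or over the list alone (3 at an unadjusted p under 0.05) and did not pass (median -0.38, camera adjusted p = 0.119), with CYCB1;2 (AT5G06150) at -0.87, CYCD3;1 (AT4G34160) at -0.66, CYCB1;1 (AT4G37490) at -0.61 and CDKB1;1 (AT3G54180) at -0.42.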

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

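All tests of explanations in this part were chosen after the results had been seen. Signals outside the main measurement differed between the groups in 2 ways. The 6 bright spike-in probes, RNA added in set amounts to each labelling reaction, were higher on the inoculated arrays by a mean of 0.41 log2 units (0.27 to 0.52 per probe), although the first inoculated array was the dimmest for plant RNA. Set against the spike-ins, its 75th percentile lay at -2.34 log2 units, while the other 3 arrays lay between -0.80 and 0.15. In the authors' deposited matrix the 2 inoculated columns held the same values in all 33300 rows, and the 2 control columns were identical in 0 rows.

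Many genes differed between groups that lay on separate slides, with a dim array in 1 of them. Most of the 1789 called features were called again without the dim array, but this cannot decide whether that array accounts for them. The features had been called with it. The refit also took its spread from the control pair alone, which differed less than the inoculated pair (SD of the difference 0.45 against 0.62). A batch of growth, harvest, RNA preparation, hybridization or scanning that came with the slide cannot be told apart from inoculation, since 0 slides held both groups, and inoculation itself stays open on the same ground.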

How the results depend on the processing

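Calls were sensitive to how the spread was estimated, and array weights and the test of matched features were chosen after seeing the data. Of the 1789 called features, all kept their sign in every setting that tested them, except 2 of 1789 in the authors' matrix, 1 of 1788 with normexp and 4 of 1789 with the mean of all probes. Most settings could not change a sign. The groups of all 1789 did not overlap, so leaving out an array keeps it, and other settings reuse the same fold changes. Only the other scalings, the authors' matrix and the mean of all probes could have changed it. The count of calls moved to 2703 with normexp, 8254 in the authors' matrix (85.5% higher, against 46.3% in the main setting), 3119 with eBayes trend and robust options and 0 without the filter on dim probes (limma, 6033 at an unadjusted p under 0.05). It ranged from 0 to 4232 with each array left out in turn. In the settings that kept the count within 1.5 times, it lay between 1517 (mean of probes) and 2195 (matched features alone). With the array position as a replicate block limma called 0 features (6270 unadjusted, smallest adjusted p 0.0885). Samples of the same number did not deviate together (correlation -0.08 over features), which gives no sign of pairing but cannot exclude it. Of the 79 named genes that were called, 75 were called again with quantile normalization, 78 with the median, 71 with normexp, 63 in the authors' matrix, 77 without inoculated 1 and 78 without inoculated 2, but 0 without control 1, without control 2, without the filter and with the block. The 14 shifted lists became 0 with an estimated correlation and between 11 and 16 in the other settings. In the authors' matrix camera turned 2 of them downward, jasmonate (median 0.28, adjusted p 0.447) and abscisic acid, drought and cold (median 0.23, adjusted p 0.442), while their medians stayed positive. The authors' matrix was not filtered for dim probes. The median of all features was 0.26 there and 0.15 without the filter, against -0.04 in the main setting, so both list medians lie close to that of all features. The cause was not tested for these changes. Set by the design were the fewer samples when arrays are left out. Camera with an estimated correlation also rested on 2 residual degrees of freedom. Fits without an array assume that the lone sample of its group varies like the other group. Between 66.6% and 72.4% of probes were well above background per array, and 155 called features were so on 0 arrays of 1 group, which makes their folds lower bounds.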

Other observations

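All tests in this part were chosen after the results had been seen. Gene families, taken from the letters that open a gene symbol, were tested for an excess of called genes with Fisher's exact test (one-sided, 240 tests over 120 families of at least 10 measured genes, among 19669 matched genes). Genes of a family are not independent, and the calls are those of the main setting. The XTH family, whose enzymes cut and rejoin wall xyloglucan, had 7 of 22 members higher and 1 lower (adjusted p = 0.00201). XTH15 was 11.3-fold and XTH25 9.14-fold higher, beside the XTH17, XTH18 and XTH19 already given. The family also had 7 members higher under each of the 3 other scalings and in the authors' matrix. The symbols HB, of homeobox genes, had 6 of 33 members higher (adjusted p = 0.0423), with HB-3 at 4.53-fold, HB53 at 4.49-fold and HB21 at 3.00-fold; 4 to 6 were called higher under the other scalings and 6 in the authors' matrix. Without control 1, or without control 2, limma called 0 features in all (3676 and 5272 at an unadjusted p under 0.05), those of every family here included.

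Some families of conjugation and transport held more genes called lower than chance gives, although most of their members were not called. UDP-glycosyltransferases whose symbol opens with UGT had 10 of 48 members lower and 2 higher (Fisher's exact test, adjusted p = 0.00471). Those lower included the flavonol glycosyltransferase genes UGT78D2 (6.44-fold), also in the flavonoid list, and UGT78D1 (4.73-fold) and the sinapate glycosyltransferase gene UGT84A2 (3.84-fold). UGT79B1 and UGT74C1, given above as lower, have other symbols among the gene names used and are not in the 48. The family's median log2 fold change was -0.41, against -0.56 without inoculated 1 and -0.23 without inoculated 2. The UGT genes called lower numbered 6 with quantile normalization, 8 with the median, 8 with normexp, 6 in the authors' matrix and 7 with array weights. Tau-class glutathione transferases (GSTU) had 6 of 22 lower (adjusted p = 0.021) and the ABCC transporters 5 of 15 lower (adjusted p = 0.021), with ABCC4 at 5.17-fold and ABCC2 at 2.28-fold. Under the 3 other scalings 5 to 6 GSTU and 4 to 5 ABCC genes were called lower. Without inoculated 1, 5 GSTU genes were lower and 1 higher and 3 ABCC genes were lower, and without inoculated 2, 10 GSTU and 8 ABCC genes were lower. B-box genes (BBX), many of which act in light signalling, had 5 of 16 lower and 1 higher (adjusted p = 0.0236), with BBX32 at 4.55-fold and BBX19 at 4.23-fold. Their median of -0.31 became 0.14 when all 4 arrays had to be above background, -0.49 without control 1 and -0.13 without control 2; without inoculated 2, 7 were lower and 3 higher. The mitochondrial RNA editing factors (MEF) had 4 of 12 lower (adjusted p = 0.0489), but 1 with quantile normalization and 0 with normexp.

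Higher DIN1 and ASN1 raised the hypothesis that less light or carbon reached the inoculated shoots. Of 15 other measured markers of sugar starvation and darkness, 8 were called higher, led by DIN10 (log2 fold change 3.05), MGL (2.71) and TPS11 (1.79), and DIN11 was called lower (-1.87). Their median of 1.42 lay above those of all 10000 random lists matched on signal, as a shortage of light or carbon would need. The random lists held genes drawn singly, while these markers respond to the same conditions as DIN1 and ASN1. Their rise in the same arrays is therefore not independent support for the hypothesis. A later harvest within the same light period would need these markers, which are known to fall in the light, to be lower. Of the 15, 12 were positive, while DIN11, BT2 (-1.13) and DIN9 (-0.17) were negative. The lower 2.5% bootstrap bound of their median was 0.95. That bootstrap resampled genes and not plants or harvests, so it cannot exclude a later harvest. Whether a shortage, if present, came from the fungus or from the growth conditions of that batch was not tested.

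Lower LHY and CCA1 beside higher PRR9, PRR5 and GI raised the hypothesis that the inoculated shoots were harvested at a later time of day. Among further clock-controlled genes, the 3 that peak by day (PRR7, PRR3, CHE) exceeded the 9 that peak around dawn by 2.30 log2 units on average (exact one-sided permutation test over 220 arrangements, p = 0.0364), as a later harvest would need. The test shuffled genes as if independent, although the same clock drives them and the genes that raised the hypothesis. It is therefore not independent support, and its p measures no spread between harvests. COL2 (-3.06), CDF2 (-2.34) and COL1 (-1.18) were called lower, while EPR1, also a dawn gene, was called higher (3.05). The rest of the 9 dawn genes were not called, and of the 3 day genes only PRR7 (3.15) was. Inoculation itself changing the clock cannot be told apart from this, since 0 labels give a harvest time of day.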
